A study of Mus musculus with 3 samples.

How the data were processed

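Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was applied to neurospheres, which are floating cultures that grow from neural stem cells. The cells were taken from the subventricular zone of wild-type male C57BL/6 mice, the zone along the lateral ventricles where neural stem cells persist in the adult brain. The series holds 3 samples with 1 library each. The first was precipitated with an antibody to H3K4me3, the histone H3 lysine 4 trimethylation found at active and poised promoters. The second was precipitated with an antibody to H3K27me3, the histone H3 lysine 27 trimethylation laid down by Polycomb repressive complex 2. The third was input DNA with no antibody, which was not analysed here. Groups were taken from the antibody named in the labels, and from the title for the input.

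For each mark the authors deposited a list of regions with a start, an end and a score. Bowtie 1.1.2 and the mouse genome build mm9 are named in the submitters' processing notes. The regions carry MACS peak names, per the deposited files. The MACS version, the calling threshold, any read filter and the use of the input as a control are not given in the sources used here. The deposited score has no stated scale. In MACS output this place usually holds a multiple of the negative logarithm of a p-value. The scores start at 50.01 for H3K4me3 and 50 for H3K27me3 and pile up at 3100, so 3100 and above is called the top score below. Scores were compared only within a list, never between the lists, since a score depends on the depth and background of its own library. Read counts and sequencing depths were not used here, so no value carries a depth and no sample carries a detection limit. The region numbers in the H3K27me3 list run to 117514, and 2 of them are absent from the list as used. Positions are given on mm9, counted from 1.

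A region was counted as overlapping when it shared at least 1 bp with a region of the other list. The overlap was compared with 1000 circular rotations of the H3K27me3 list within each chromosome, with a fixed seed, which keep the spacing and widths of the regions. The chromosome length used was the last region end in either list. The p-value is two-sided, and 0.0020 is the smallest that 1000 rotations can give. Widths of regions were compared by a two-sided permutation test of the difference of medians with 100000 resamples, whose smallest p is 1e-05. Shares were compared by Fisher's exact test, two-sided. Intervals of a share of regions are 95% Wilson intervals, and those of a difference of 2 shares are 95% intervals from the normal approximation. They cover counting error only. With 1 library per mark there is no replicate error, and each test compares regions of these 2 lists, not cultures or animals. Neighbouring regions are not independent, while the intervals, Fisher's exact tests and permutation tests of medians treat regions as independent. These intervals are therefore too narrow and these p-values too small. H3K27me3 domains were made by merging regions over gaps of up to 3000 bp. Densities were set over the 19 autosomes, and their spread is that between chromosomes.

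Before the data were examined, the main comparisons, the alternatives listed below and the rule for named items were fixed. For these lists the plan held the rotation test of overlap, the median test of widths, and chromosome densities with no test. The tests between score classes, of domains, of the relation between chromosome densities, and of X against autosomes were not in that plan. Without gene positions on mm9 the rule names the 10 widest H3K4me3 regions and the 10 longest H3K27me3 domains by coordinates. The gene table at hand is of GRCm38.p6, another build, so its positions were not joined to these regions. The planned comparisons of coding promoters, long noncoding RNA (lncRNA) promoters and fixed gene lists were therefore not made, and no gene is named. The alternatives tried were a minimum overlap of 200 bp or of 50% of the H3K4me3 region, the upper 50% of each list by score, merged H3K27me3 regions, and autosomes only. Because over 50% of H3K4me3 regions tie at the top score, the upper part of that list is all 11564 of them. Widths were also compared after merging both lists over gaps of up to 3000 bp.

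Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used. Overlap counts and shared base pairs were checked against bedtools 2.31.1 and differed by 0. The rotation test was tested on simulated data made with the 696 H3K4me3 regions and 2993 H3K27me3 widths of chromosome 19. It gave p under 0.05 in 1 of 100 simulated pairs of lists with no relation, and in 100 of 100 with 30% of the H3K4me3 regions given an overlap. The simulation took over the widths of H3K27me3 regions but not their clustering. It also did not let the marks favour the same parts of a chromosome. These runs therefore do not show how often the test errs on lists like the real ones. In simulated widths the median test gave p under 0.05 in 3 of 100 runs with no difference, and in 100 of 100 with medians 20% apart.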

Results

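The study asked which chromatin state marks promoters, above all those of lncRNAs, in adult neural stem cells. The H3K4me3 library gave 21998 regions, and the H3K27me3 library gave 117512. The regions of the marks, as called, differed in form. H3K4me3 regions had a median width of 1988 bp (interquartile range 1156 to 2841 bp) and covered 47.9 Mb. H3K27me3 regions had a median width of 878 bp (interquartile range 696 to 1315 bp) and covered 150.7 Mb. They spread over 5.68% of the assembled chromosomes, against 1.80% for H3K4me3. Many H3K27me3 regions lay close together in longer domains, described below. Their number and width, and shares counted over them, therefore depend on how they were called. The top score was reached by 11564 H3K4me3 regions (52.6%) and by 3002 H3K27me3 regions (2.55%). There was 1 library per mark, so none of the values below has a replicate error.

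The first comparison asked how often the active and the Polycomb mark were found at the same place. H3K27me3 lay on 7363 of the 21998 H3K4me3 regions, or 33.5% (95% interval 32.9 to 34.1%). The other 14635 regions (66.5%) carried H3K4me3 alone. Seen from the other mark, 8325 H3K27me3 regions (7.08%, 95% interval 6.94 to 7.23%) touched an H3K4me3 region, and 109187 (92.9%) did not. The 2 lists shared 9.64 Mb, which was 20.1% of the base pairs in H3K4me3 regions and 6.40% of those in H3K27me3 regions. When the H3K27me3 list was rotated along each chromosome, 12.7% ± 0.536 (SD over 1000 rotations) of H3K4me3 regions overlapped it. The observed overlap was 2.63 times that mean, above the highest rotation at 14.9% (two-sided permutation p = 0.0020, the smallest possible). Against the local neighbourhood the ratio was lower. When each H3K4me3 region was instead moved by 50 to 500 kb, 20.5% ± 0.244 (SD over 1000 draws) overlapped, and the observed share was 1.63 times that mean (permutation p = 0.0020). The libraries came from bulk cultures, so an overlap does not show that both marks sat on the same allele or in the same cell.

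At regions with both marks, H3K27me3 usually covered most of the H3K4me3 region. The median covered share was 84.1%, and 5563 of the 7363 regions (75.6%) were covered over at least 50% of their length. H3K27me3 covered the whole H3K4me3 region in 2101 cases (28.5%, 95% interval 27.5 to 29.6%). It reached in over 1 end only in 2963 cases (40.2%, 39.1 to 41.4%). It lay wholly inside the H3K4me3 region in 1703 cases (23.1%, 22.2 to 24.1%). In 596 cases (8.09%, 7.49 to 8.74%) it covered both ends and left a gap in between. Fully covered H3K4me3 regions were seldom among the top-scoring ones, with 14.2% at the top score. Of those with H3K27me3 wholly inside, 58.3% were at the top score. Width moved with this contrast, since the fully covered regions had a median width of 1393 bp and those with H3K27me3 inside 2124 bp, while top-scoring H3K4me3 regions were wide in general (median 2771 against 1127 bp).

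High-scoring H3K4me3 regions carried H3K27me3 less often than the rest. The share with both marks was 23.6% (95% interval 22.8 to 24.3%) of the 11564 regions at the top score. It was 44.5% (43.5 to 45.4%) of the 10434 regions below it. The difference was -20.9 percentage points (95% interval -22.1 to -19.7, odds ratio 0.385, Fisher's exact test over regions p = 1.5e-237). For H3K27me3 the order was the opposite. Of its 3002 top-scoring regions 50.5% (48.7 to 52.3%) touched H3K4me3, against 5.95% (5.81 to 6.08%) of the other 114510. The lowest decile of H3K27me3 regions by score touched H3K4me3 in 2.79% of cases and the highest decile in 28.8%. Top-scoring H3K27me3 regions were also wider, with a median of 5672 bp against 867 bp, and score and width were not separated for this mark.

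H3K4me3 regions with both marks had a median width of 1680 bp, and those with H3K4me3 alone had a median of 2200 bp (difference -520 bp, permutation test p = 1e-05, the smallest possible). The share with both marks rose from 29.5% (95% interval 27.6 to 31.4%) in the narrowest decile to 51.4% (49.3 to 53.5%) in the fourth, where the median width was 1456 bp. It then fell to 19.9% (18.2 to 21.6%) in the ninth, at a median width of 3340 bp, and was 24.95% (23.2 to 26.8%) in the widest decile. The direction of the width difference depended on the score. Among top-scoring H3K4me3 regions, those with both marks were 152.5 bp narrower (2652 against 2804 bp, permutation p = 1e-05). Among the others they were 233 bp wider (1273 against 1040 bp, permutation p = 1e-05). The difference of -520 bp therefore does not hold among lower-scoring regions. Wider regions have more room for a chance overlap, which by itself makes regions with both marks wider. The permutation test does not allow for this, and widths were not set against rotations. How much of the 233 bp, or of the change of direction, goes beyond chance is therefore not known.

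**Figure D1:**
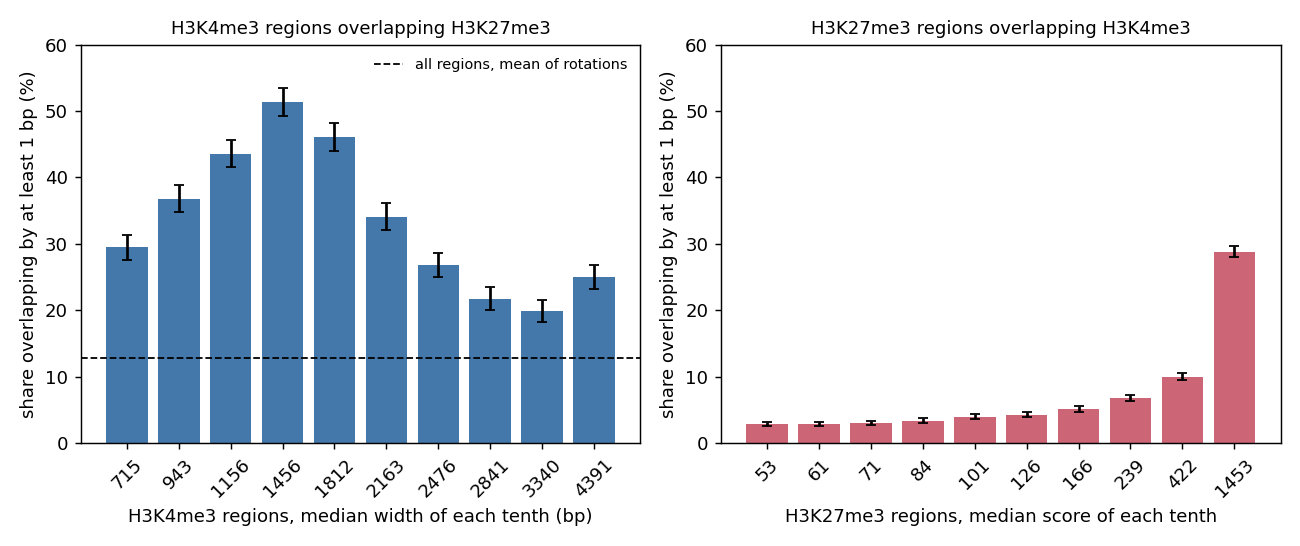
Left, the share of H3K4me3 regions that overlap H3K27me3 (%), in deciles of H3K4me3 width labelled by their median width in bp. Right, the share of H3K27me3 regions that overlap H3K4me3 (%), in deciles of H3K27me3 score labelled by their median score. Error bars are 95% Wilson intervals, and the dashed line is the mean of 1000 rotations over all H3K4me3 regions (12.7%). Wider regions overlap more often by chance, so this line is not the chance level of any single decile. The left share peaks at 51.4% in the fourth decile, and the right share climbs to 28.8% in the last.

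The surroundings of the classes of H3K4me3 regions also differed. Within 1 kb of the ends of regions with both marks, 44.7% of base pairs lay in H3K27me3 regions, and 15% still did at 50 to 100 kb. Around regions with H3K4me3 alone the value was 2.32% within 1 kb, 5.38% at 5 to 10 kb and 8.99% at 50 to 100 kb. The mean over the assembled chromosomes was 5.68%. The values next to the ends follow in part from the definition of the classes, since any region with H3K27me3 across an end belongs to the class with both marks. Of the 14635 H3K4me3-only regions, 1241 (8.48%, 95% interval 8.04 to 8.94%) had an H3K27me3 region within 1 kb and 6063 (41.4%, 40.6 to 42.2%) within 10 kb. The median distance to the nearest one was 14.6 kb. For H3K27me3-only regions the median distance to the nearest H3K4me3 region was 30.5 kb. The lists differ in their number of regions, so these distances cannot be set against each other.

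**Figure D2:**
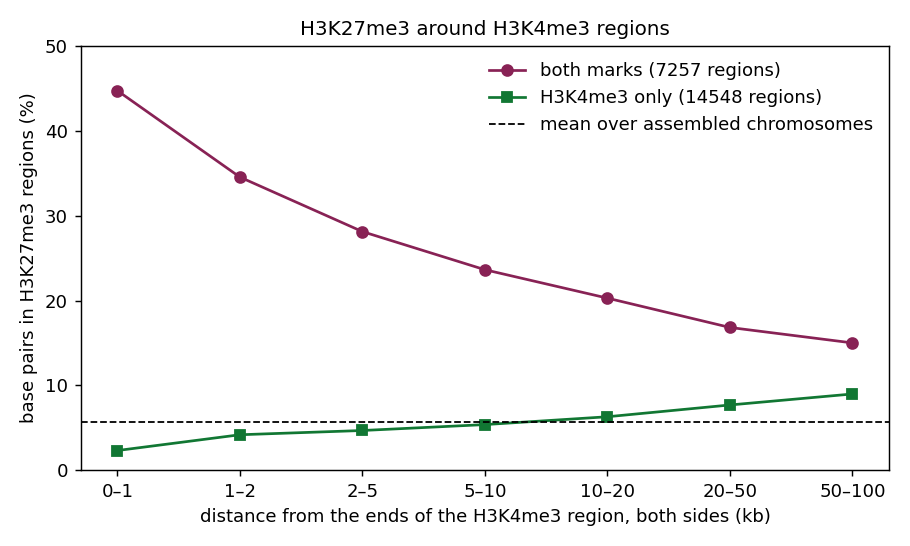
Share of base pairs lying in H3K27me3 regions (%) by distance from the ends of H3K4me3 regions (kb, both sides together), for the 7257 regions with both marks and the 14548 with H3K4me3 alone on assembled chromosomes. The dashed line is the mean over assembled chromosomes (5.68%). Around regions with both marks the share declines from 44.7% to 15%, and around H3K4me3-only regions it goes from 2.32% to 8.99%.

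Merging over gaps of up to 3 kb turned the H3K27me3 list into 53714 domains. Of these, 36038 (67.1%) were 1 isolated region. Domains of 10 kb or more numbered 4467 and held 55.2% of all base pairs in H3K27me3 regions. H3K4me3 was found in 1898 of these 4467 (42.5%, 95% interval 41.0 to 43.9%), and 2569 had none. Long domains contained H3K4me3 more often, at 39.6% of those from 10 to 50 kb, 67.5% of those from 50 to 100 kb and 83 of the 103 (80.6%, 71.9 to 87.1%) of 100 kb or more. A longer domain offers more room for a chance overlap, which rotations allow for. Rotations do not allow for marks that favour the same parts of a chromosome. For all regions the ratio was 2.63 against rotations and 1.63 when H3K4me3 regions were moved by 50 to 500 kb. The ratios by length that follow are against rotations only. The number of H3K4me3 regions touching domains was 1.62 times the mean of 1000 rotations for domains under 1 kb, 3.74 times at 1 to 5 kb, 3.08 times at 5 to 10 kb, 2.75 times at 10 to 50 kb and 2.10 times at 50 to 100 kb (two-sided permutation p = 0.0020 in each). For the 103 longest it was 1.37 times (two-sided permutation p = 0.044, not corrected for the 6 length classes). These tests by length class were chosen after the data were seen. Domains of 10 kb or more took in 13.0% of all H3K4me3 regions, 2.45 times the 5.32% ± 0.411 (SD) of 1000 rotations (two-sided permutation p = 0.0020).

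The ends, lengths, ranks and length classes of domains depend on the merging gap of 3 kb, which was not varied for them. The longest domain spanned 380.0 kb on chromosome 8, from 123239640 to 123619627, with further H3K27me3 regions ending at 123236443 and starting at 123623788. It was built from 115 regions that covered 80.8% of it, and 5 H3K4me3 regions lay inside. The next was 371.2 kb on chromosome 6 (99807079 to 100178281) with 3 H3K4me3 regions. The third was 314.6 kb on chromosome 4 (153778990 to 154093548), also with 3. A domain of 307.1 kb on chromosome 9 (61314869 to 61621927) held no H3K4me3 region, although 85.6% of it was covered by H3K27me3. Domains of 276.0 kb on chromosome 2 (31152311 to 31428288) and 262.3 kb on chromosome 15 (102716138 to 102978400) held 3 and 4 H3K4me3 regions. The rest of the 10 longest were at chromosome 4 from 134507175 to 134740023, chromosome 5 from 112257196 to 112489710 and from 111892314 to 112113822, and chromosome 11 from 118348382 to 118568214. Among these only the chromosome 5 domain that starts at 111892314 held H3K4me3, in 1 region. What genes these places hold was not analysed here.

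**Figure D3:**
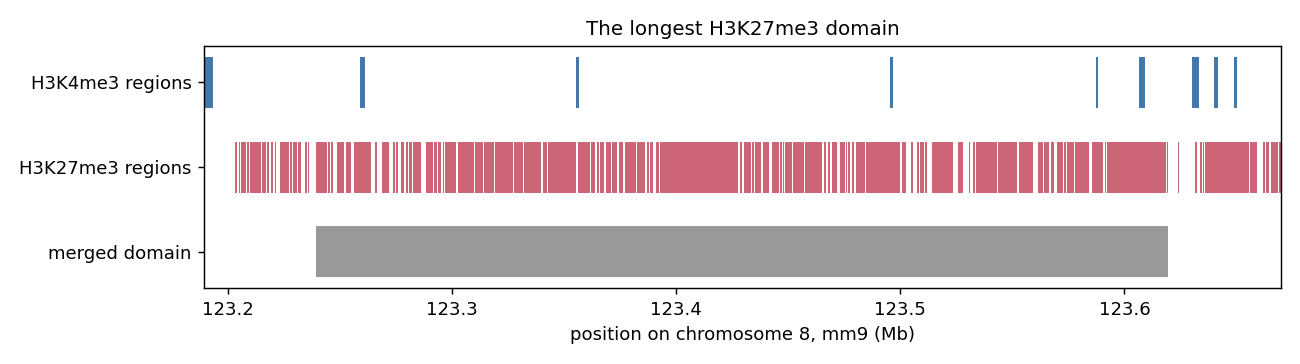
Map of the longest merged H3K27me3 domain (grey) on chromosome 8, mm9, with 50 kb on either side, to scale in Mb. The deposited H3K27me3 regions are in red and the H3K4me3 regions in blue. Inside the grey bar, 115 H3K27me3 regions and 5 H3K4me3 regions (982 to 2859 bp wide) lie between 123239640 and 123619627.

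The 10 widest H3K4me3 regions fell into 2 kinds. H3K27me3 covered at least 90.3% of the length of 6 of them. These were a 39.0 kb region at the start of chromosome 9 (2999824 to 3038816), 3 adjoining regions of 19.999, 32.0 and 35.7 kb on chromosome 8 between 126060789 and 126148670, a region of 20.5 kb on X (166426692 to 166447213) and a region of 15.5 kb near the start of chromosome 11 (3022657 to 3038153). Of these 6, only the chromosome 9 region had both ends within 100 bp of those of an H3K27me3 region. Whether extra copies of sequence raised both libraries at these places was not tested. The other 4 had no H3K27me3. They lay on chromosome 3 (88007890 to 88027586, 19.7 kb), chromosome 1 (42740403 to 42759721, 19.3 kb), chromosome 2 (115881007 to 115899079, 18.1 kb) and chromosome 4 (82142074 to 82159866, 17.8 kb). H3K4me3 regions over 5 kb numbered 606, and 29.2% of them (95% interval 25.7 to 33.0%) overlapped H3K27me3.

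The last comparison described where the marks lay among chromosomes. H3K4me3 regions had a density of 8.65 ± 1.72 per Mb (SD over 19 autosomes), from 6.45 on chromosome 1 to 13.1 on chromosome 11. H3K27me3 regions had a density of 46.8 ± 12.7 per Mb, from 26.9 on chromosome 3 to 78.0 on chromosome 11. Autosomes with more H3K4me3 regions per Mb had more H3K27me3 regions (Pearson r = 0.85, permutation p = 2e-05; Spearman rho = 0.78, permutation p = 0.00025; 1 relation tested). Without chromosomes 11 and 19, the farthest from the median H3K4me3 density, r was 0.84. The X chromosome lay below every autosome for both marks. It had 4.21 H3K4me3 regions per Mb, 0.486 times the autosomal mean, and 8.64 H3K27me3 regions per Mb, 0.185 times the autosomal mean. H3K27me3 regions at the top score numbered 17 on X, or 0.102 per Mb, against 1.19 ± 0.486 per Mb (SD over 19 autosomes). Both marks were found together on 143 of the 701 H3K4me3 regions of X (20.4%, 95% interval 17.6 to 23.5%), against 33.7% (33.1 to 34.4%) on autosomes (Fisher's exact test over regions p = 2.4e-14). H3K27me3 regions covered 0.942% of X and 5.99 ± 2.06% of autosomes (SD over 19 autosomes), so fewer chance overlaps are expected on X. No rotation share was computed for X alone. The mean of rotations was 2801 overlapping H3K4me3 regions over the whole list and 2769 over autosomes only, in separate runs. X can thus add only a small part of that mean, less than the 143 regions observed on it. The lower share on X therefore does not show less overlap relative to chance, and a ratio for X was not tested. The Y chromosome held 6 H3K4me3 and 14 H3K27me3 regions, too few to compare.

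**Figure D4:**
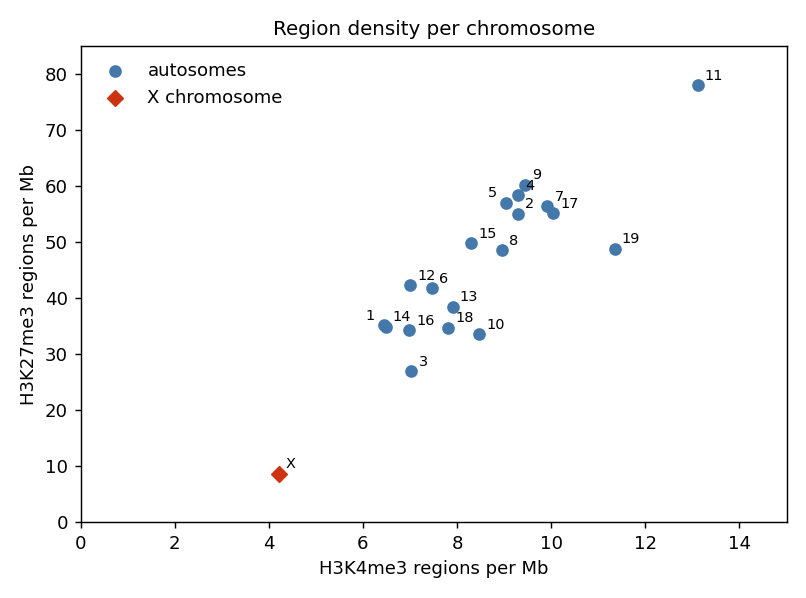
H3K4me3 regions per Mb (horizontal axis) against H3K27me3 regions per Mb (vertical axis), 1 point per chromosome, with autosomes in blue and X as a red diamond. Y is left out. Chromosome 11 is highest for both marks (13.1 and 78.0 per Mb), and X is below every autosome for both (4.21 and 8.64 per Mb).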

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

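The excess of overlap over rotations kept its direction and its p of 0.0020 under all 7 alternatives, with ratios from 1.63 (H3K4me3 regions moved 50 to 500 kb) to 4.68 (at least 50% of the H3K4me3 region covered). That move, the removal of unplaced contigs and same-ended regions, and the widths within score classes were chosen after seeing the data. The share of H3K4me3 regions with H3K27me3, 33.5% as reported, was 25.3% when 50% of the region had to be covered, 32.4% when 200 bp had to be shared, 18.7% in the upper 50% of each list by score, 34.1% with H3K27me3 regions merged, and 32.4% without unplaced contigs and same-ended regions. The fall to 18.7% goes with the construction of that alternative, which keeps only top-scoring H3K4me3 regions and drops H3K27me3 regions. On autosomes the share was 33.7%, within its interval. The width difference of -520 bp was -566 bp with merged regions, -528 bp on autosomes and -152.5 bp among top-scoring H3K4me3 regions. It turned to 233 bp wider with both marks among lower-scoring ones. Wider regions overlap more often by chance, these widths were not set against rotations, and the cause was not tested. The low density on X was 0.148 (H3K27me3) and 0.467 (H3K4me3) times the autosomal mean in the upper 50% by score. There the share of H3K4me3 regions with both marks was 5.60% on X (20 of 357) and 19.1% on autosomes (Fisher's exact test over regions p = 4.9e-13), so its ratio to the autosomal mean went from 0.608 to 0.292, and the cause was not tested. In that part H3K27me3 covered 0.573% of X, against a mean of 4.29% over autosomes. These shares were not set against rotations of X alone. The alternatives planned for coding promoters, lncRNA promoters and gene lists were not run, because no gene positions on mm9 were used here. No paired analysis was possible because each mark has 1 library. Sequencing depth, which sets how many weak regions a caller can find, is not known here, so neither the number of regions nor the absence of a mark at a region can be set against a detection limit.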

Other observations

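Long H3K27me3 domains were rare on X. Domains of 10 kb or more numbered 25 on X, out of 4467 in all, and none of the 103 domains of 100 kb or more lay there. H3K4me3 regions of X had a median width of 1966 bp, within the autosomal range of 1678 to 2159 bp, and 50.9% of them were at the top score, within the autosomal range of 45.6 to 58.2%. Below the top score the median score of H3K4me3 regions was 435 on X and ran from 207 to 296 on autosomes.

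The tests in the paragraphs that follow were all chosen after the patterns had been seen in these data.

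The first pattern is the low density of H3K27me3 on X, 8.64 regions per Mb against 26.9 on the lowest autosome. Fewer H3K4me3 sites on X do not account for all of it. In 1 Mb windows matched on their number of H3K4me3 regions, X had 0.290 times the H3K27me3 regions of other chromosomes. The autosomes ran from 0.652 to 1.25 on the same measure. Over whole chromosomes X had 0.185 times the autosomal mean density, so a part may go with the number of H3K4me3 sites. The windows used held 1234 of the 1440 H3K27me3 regions of X. A single X copy per male cell would lower reads and perhaps scores on X and stays open, since the median H3K27me3 score was 93.5 on X, below the autosomal range of 97.7 to 126, while the H3K4me3 scores above were not lower, and X held 0.663 times the regions of the lowest autosome even when the autosomal score cutoff was doubled to 100. Without a matched control, weak regions could lose more than that, and the control behind the calls is not known. A chromatin difference of X in these cells is open as well and was not tested.

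The second pattern is that H3K27me3 overlap was more frequent at lower-scoring H3K4me3 regions, and in each of the 8 width deciles with at least 20 regions of either score class, the third to the tenth, the top-scoring regions had the lower share, while the 2 narrowest deciles held 1 and 7 top-scoring regions and cannot show it (42.9% of 7 against 36.8% of 2193 in the second). Background reads from accessible chromatin in the H3K27me3 library, if they follow H3K4me3 strength, would make overlap more frequent at top-scoring regions, the reverse of the pattern, so whether such background is present stays open. A pair of tests tried in turn does not decide it, since the first, the difference of shares (-20.9 percentage points), is the pattern itself, and the second, the median of the highest overlapping H3K27me3 score (434 at top-scoring regions and 641 at the others, a difference of -207, permutation p = 1e-05), runs only on regions already chosen for their overlap. Repeats or extra copies that raise both libraries stay open too, since without unplaced contigs and same-ended regions the difference of shares was -19.4 points (95% interval -20.7 to -18.2), but that removal took 355 of the 4639 lower-scoring regions with both marks, while about 2853 would have to go to close the gap. Weaker H3K4me3 at places with both marks and a mix of cells that carry 1 mark each may both apply, untested.

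The third pattern is a set of 305 H3K4me3 regions whose ends both lie within 100 bp of those of an H3K27me3 region, the widest at the start of chromosome 9. Sequence present in more copies than in the assembly would raise both libraries alike. On unplaced contigs, where such sequence is often placed, 15 of 106 regions with both marks had the same ends (14.2%), against 290 of 7257 (3.996%) on assembled chromosomes (odds ratio 3.96, Fisher's exact test over regions p = 2.7e-05). Of the 305, 11.8% were at the top H3K4me3 score, against 38.1% of all regions with both marks. They were also narrower (median 887 against 1680 bp), and score and width were not separated here. The higher share on unplaced contigs leaves extra copies as a candidate source for some of these pairs. For the 290 on assembled chromosomes (median width 887 bp) no biological explanation was tested.

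Unplaced contigs held 191 H3K4me3 regions, of which 55.5% overlapped H3K27me3. The widest H3K27me3 region, 89.2 kb on chromosome 8 from 126060716 to 126149888, was covered by H3K4me3 over 98.3% of its length. The H3K4me3 list also holds 2 regions on the mitochondrial genome, which carries no histones, at 12059 to 13245 and at 14067 to 14940, with low scores of 98.4 and 55.0. The H3K27me3 list holds 0 there.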
